A study of Mus musculus with 5 samples.

How the data were processed

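Total RNA of cultured mouse marrow mesenchymal stem cells was sequenced as 5 Illumina libraries, knockout 1, 2 and 3 and wild type 1 and 2, per the labels. The authors deposited 1 table per library with an expected count, an FPKM and a length for each gene, per the file headers. The headers name them expected counts, as RSEM does, whose estimates share out a read that fits several genes. The relation of the deposited FPKM values to those counts was worked out here from the values. It is a scaling by library size and by gene length less an implied 132.3 to 134.8 bases. Each gene's length column gives bases. HISAT2, StringTie, Bowtie2 and RSEM and the build mm10 are named per the submitters' processing notes, with no versions and no roles. The genes carry Entrez identifiers, symbols and pathway and Gene Ontology terms in the deposited tables. Some genes also hold transcripts that are not in RefSeq.

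The tables list 10785 to 11493 genes per library and 14161 in any, and a gene missing from a library was taken as 0 counts. Expected counts sum to 226695, 237088 and 281990 in the knockout and 243072 and 211623 in the wild type libraries. The listed counts come to 76.6% to 80.1% of the read total implied by the FPKM values, so part of the counted reads lies outside the listed genes. Of the listed values, 93.8% to 94.2% were whole within 0.005. Counts were rounded to whole numbers. The limit for a count of 0 was taken as 3 counts; this and all Poisson intervals (95%) cover counting error only.

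The 3 knockout libraries were compared with the 2 wild type libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10, minimum total 15), TMM scaling, robust quasi-likelihood fits with genotype as the term, and Benjamini-Hochberg adjustment at 0.05. Levels are CPM over the TMM-scaled totals of the tested genes. Standard errors of log2 fold changes were derived from the quasi-likelihood F. Arntl, all listed clock genes, tested named genes with at most 3 counts in a group and genes chosen after their values were seen were also compared by exact two-sided Poisson tests of summed counts; other genes too low to test are given as counts. DESeq2 1.42.0, limma 3.58.1 and sva 3.50.0 served for alternatives.

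Before the data were examined, 36 gene lists were fixed: clock output and other core clock genes, matrix metalloproteinases, protease inhibitors, ADAMTS and lysyl oxidases, collagens, osteoblast, chondrocyte and adipocyte genes, stromal progenitor markers, NF-kB and interferon targets, BMP and TGF-beta, WNT, cell cycle, cell cycle inhibitors, NRF2, hypoxia and glycolysis, respiratory chain, cholesterol, unfolded protein and contractile genes. Further lists held markers of osteoclasts, macrophages, neutrophils, B, T and NK, erythroid, megakaryocyte and mast, endothelial and muscle cells, and immediate-early, ribosomal, mitochondrially encoded, histone and sex-linked genes. The 21 lists with 5 or more tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. Of the 21, 11 passed with the preset correlation, 0 with an estimated one (6 at an unadjusted p under 0.05) and 18 with fry, which tests whether a list's genes move one way and not whether they differ from other genes. For some of these lists the estimated correlation lay below the preset 0.01, so a call lost with it need not reflect correlation between genes. Members were also adjusted over the list alone. With a library left out the tested members of a list can change, so list medians and counts then may cover other genes.

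Terms of 10 to 500 tested genes were tested among the higher and the lower genes, each by a hypergeometric test against all tested genes with a term. The named genes were fixed by a rule before the data were examined. It takes Arntl and Mmp3, and the 10 largest rises and 10 largest falls past the test with separate groups, at least 10 CPM in the higher group and a symbol that is no gene model. It adds up to 2 genes per direction of each list by adjusted p (the 2 smallest p where none passed), all tested clock genes and the 2 highest members of each marker list. Further members of the fixed lists that are given, such as Col8a1, Adamts5, Cd36, Hk2 and Irf7, were picked outside this rule. They are not part of the count of named genes with each library left out. Genes outside both the lists and the rule are said to be chosen after their values were seen.

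Coordinates are those of mm10 from RefSeq, and 13466 genes (95.1%) matched exons of GENCODE M21, which gave the exon bases lying opposite exons of a gene on the other strand. Genes with at least 100 such bases were called opposite another gene; 1190 of the 3710 tested genes were. The strand setting of the libraries and of the counting is not given in the sources used here, so reads of such pairs cannot be told apart. Alternatives were RLE, upper-quartile and total-count scaling, DESeq2, voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with genes at 1 FPKM in 2 libraries or with no filter, other count filters, a fold of 1.5 as the null, an adjusted p of 0.01, leaving out each library, and the replicate number as a block. On such FPKM scales a log2 difference understates the change of low genes.

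Tested on simulated data, with 10 draws of counts for these libraries and 200 genes changed in each (median 3618.5 genes tested), the comparison recovered 17.0% of genes changed 1.5-fold, 45.1% of those changed 2-fold and 78.6% of those changed 4-fold, all with the right sign, and 4.57% of its calls were false. A list planted at 2-fold was found in 10 of 10 draws, and 4 calls of lists that were not planted were made over those draws. Each gene was drawn independently at 1 dispersion common to all genes, taken from these libraries (coefficient of variation 0.092). Correlation between genes, and spread between mice beyond that of these libraries, were left out. The shares of false calls therefore hold for that setting and do not measure those of the real comparison. No library was left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.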

Results

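RNA was sequenced from cultured mesenchymal stem cells of mouse femur marrow, the adherent stromal cells that can form bone, cartilage and fat. All cells came from C57BL/6 mice 6 to 8 weeks old and were used at passages 1 to 3. The 5 libraries fall into 2 groups: 3 of Bmal1-knockout cells and 2 of wild type cells. Bmal1 (gene symbol Arntl) encodes the transcription factor that pairs with CLOCK to drive the circadian clock. The knockout libraries held 226695, 237088 and 281990 expected counts, and the wild type libraries 243072 and 211623. A count of 0 in a library allowed a level of up to 12.1 to 15.9 CPM (counts per 1e6 counts; 3 counts of the scaled total of tested genes, the scale of all levels here). The comparison asks which genes depend on BMAL1 in these cells. The series names Mmp3, a secreted protease that degrades matrix, as a gene raised by its loss.

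Arntl (Entrez gene 11865, chromosome 7, 113178471 to 113314126, mm10), the deleted gene, had 4, 1 and 2 counts in the knockout libraries and 5 and 0 in the wild type libraries. Its knockout to wild type ratio was 0.854, with an exact Poisson interval of 0.233 to 3.41 (95%, counting error only). At this depth Arntl did not distinguish the genotypes and so does not check the labels. Which part of the gene was deleted is not given in the sources used here, so reads from a remaining part would also be counted.

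In the knockout libraries 12 of 16 tested collagens and 14 of 17 contractile genes were higher, and 9 of 17 macrophage genes and 6 of 19 interferon-stimulated genes were lower. These 4 lists passed a list test with a preset correlation between genes, and none of them passed with an estimated one (adjusted p from 0.106 to 0.152). The estimated correlation lay above the preset 0.01 for collagens (0.12) and contractile genes (0.22). For macrophage (-0.022) and interferon-stimulated genes (-0.013) it lay below 0.01, so correlation between genes does not account for their lost calls. The estimated setting thus raises p for other reasons too. The lost calls of collagens and contractile genes therefore cannot be laid to correlation alone. Type I and type III collagen genes, which encode the main fibrils of bone and soft tissue, rose, Col3a1 2.61-fold and Col1a1 3.10-fold. Col1a1 went from 652 ± 138 CPM (SD, n = 2) to 2008 ± 166 (n = 3). Acta2, the smooth muscle actin of myofibroblasts, rose 4.17-fold. Lyz2, the lysozyme of macrophages, fell from 10767 ± 261 to 6789 ± 282 CPM. Of 3710 genes tested, 304 were higher and 302 lower at an adjusted p under 0.05, and 172 of the higher and 162 of the lower genes differed more than 2-fold.

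**Figure D1:**
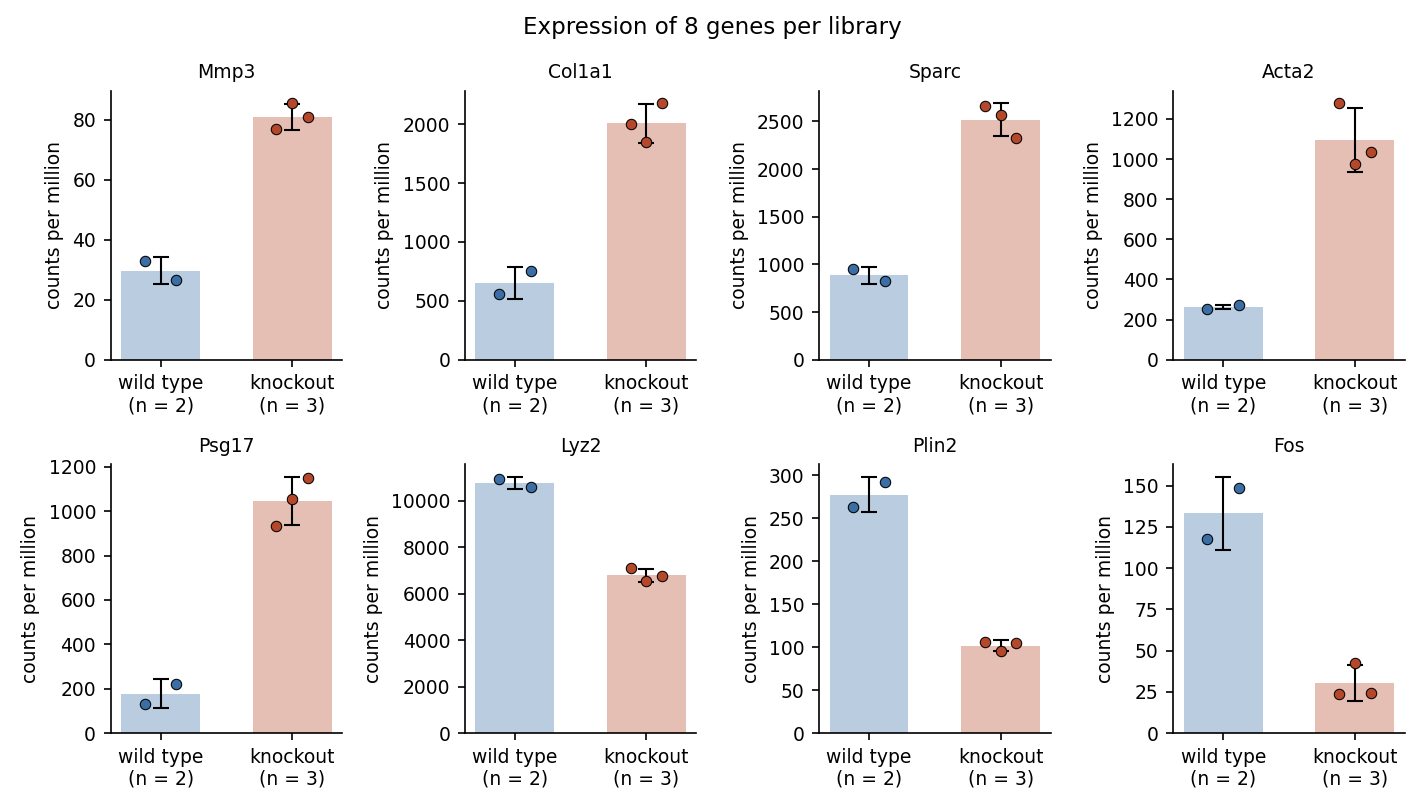
Level of 8 genes, in CPM, in each library. Points are libraries (2 wild type, 3 knockout), bars the group means and whiskers the SD, on axes that start at 0. In each panel the 3 knockout libraries lie on one side of both wild type libraries: Mmp3 lies between 76.9 and 85.6 in the knockout and at 32.9 and 26.6 in the wild type.

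Mmp3 (Entrez gene 17392, chromosome 9, 7445822 to 7455975, mm10) had 16, 18 and 20 counts in the knockout and 7 and 5 in the wild type libraries. Its level was 81.1 ± 4.35 CPM (SD, n = 3) against 29.7 ± 4.46 (n = 2), a log2 fold change of 1.42 (SE 0.47; adjusted p = 0.0187). The series chose Mmp3 on these samples, so its rise here is not independent evidence. The call was lost without wild type 1 (log2 fold change 1.57) and without wild type 2 (1.28). It was also lost with DESeq2 (1.46, adjusted p = 0.126), voom (1.36, adjusted p = 0.163), the replicate number as a block (1.42, adjusted p = 0.0594) and further settings given below. Over all settings that kept both wild type libraries, its adjusted p ranged from 0.0174 to 0.163.

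Of 23 matrix metalloproteinases, the enzymes that cut collagen and other matrix proteins, 16 were listed and 8 tested: 2 rose, 1 fell and 5 did not pass, or 3 and 1 when adjusted over the list alone. The list includes Mmp3 and so is not independent evidence of its direction. Mmp9, a gelatinase made largely by leukocytes and osteoclasts, fell (log2 fold change -0.66, adjusted p = 0.00279), a call lost without wild type 2 (-0.58, adjusted p = 0.140). Mmp24, a membrane-bound member, rose by 0.38, a call lost without knockout 3 (0.26) or either wild type library (0.42 and 0.31), and 637 bases of its exons lie opposite exons of BC029722. Mmp2, the gelatinase of stromal cells, was at 0.70 (adjusted p = 0.0597) and Mmp13, the collagenase of cartilage and bone, at -0.06 (adjusted p = 0.811). As a list the family did not differ from other genes (median log2 fold change 0.20, adjusted p = 0.578).

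Neither clock list had a member past the test with edgeR, where 0 of 6 tested members had an unadjusted p under 0.05. None of the 6 passed with voom, and Dbp, Nr1d1, Nr1d2, Clock and Csnk1d did not pass with DESeq2. Of the E-box output genes, which BMAL1 and CLOCK activate directly, 14 were listed and 3 tested: Dbp, a transcription factor of rhythmic metabolism, had a log2 fold change of -0.66 (adjusted p = 0.357), Nr1d1, which encodes the repressor REV-ERBα, 0.20 (adjusted p = 0.755), and Nr1d2, its paralog REV-ERBβ, -0.17 (adjusted p = 0.838). Without knockout 2, Nr1d1 was at -0.11, and without wild type 2, Nr1d2 was at 0.96. Exons of Dbp lie opposite Sphk2 and those of Nr1d1 opposite Thra. Of 13 other core clock genes 10 were listed and 3 tested; Clock, the partner of BMAL1, was at -0.35, and Csnk1d, a kinase of the PER proteins, at -0.19 (0.03 without knockout 3). No member passed when adjusted over the list alone. Exact Poisson ratio tests of the summed counts of all 24 listed clock genes put Per2, a repressor of the clock, at 0 counts in the knockout against 6 in the wild type, a ratio of 0 with an exact interval up to 0.518 (p = 0.00295; 0.0709 after Benjamini-Hochberg adjustment over the 24). Its wild type counts were 1 and 5, and the interval reached 0.833 without knockout 3, 0.310 without wild type 1 and 12.7 without wild type 2. Per3, another PER gene, had 15 counts against 2, a ratio of 4.57 with an interval of 1.06 to 41.2 (adjusted p = 0.304); these were the 2 genes of the 24 with an unadjusted p under 0.05. Both wild type counts of Per3 came from wild type 2. Its ratio was 2.13 (0.495 to 19.2) without wild type 1 and 4.02 (0.833 to 38.3) without knockout 2, and with wild type 2 left out the wild type had 0 counts. The same exact tests gave Nr1d1 a ratio of 1.16 (0.780 to 1.74), Nr1d2 0.902 (0.529 to 1.56) and Dbp 0.634 (0.352 to 1.14). Each interval includes a ratio of 1, so these targets of BMAL1 do not check the labels either.

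Of 19 collagens listed, 16 were tested, 12 rose, none fell and 4 did not pass, with 13 rising when adjusted over the list alone. The median log2 fold change was 1.19 (adjusted p = 1.4e-22 with camera's preset correlation; adjusted p = 0.106 with an estimated correlation). The smallest adjusted p were those of Col3a1 (log2 fold change 1.38, SE 0.11, adjusted p = 3.8e-33) and Col1a1 (1.63, SE 0.13, adjusted p = 1.8e-32). Col8a1, a short-chain collagen, rose by 1.84, and Col4a1, a basement membrane chain, by 1.27. Summed over the list, the knockout libraries held 15125 ± 715 CPM (SD, n = 3) and the wild type libraries 5919 ± 251 (n = 2). The macrophage genes summed to 11223 ± 583 against 17350 ± 199 in the same libraries.

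Of the ADAMTS and lysyl oxidase family, proteases and collagen cross-linking enzymes, 17 were listed and 6 tested, and 4 rose with none falling, gene-wide and when adjusted over the list alone. Lox, which cross-links collagen and elastin, rose 2.78-fold from 526 to 1462 CPM, and Loxl2, its relative, 2.08-fold (301 exon bases opposite Gm27177). Adamts5, an aggrecanase, rose by 2.44 on the log2 scale on low counts, 17, 8 and 22 in the knockout against 4 and 1 in the wild type. The list's adjusted p was 3.6e-05, and adjusted p = 0.106 with an estimated correlation; without knockout 3 and without wild type 2, 2 members rose. Of 11 protease inhibitors of the matrix, all were listed and 8 tested; 5 rose and 3 did not pass, by either adjustment. Serpinh1, the collagen chaperone HSP47, rose by 2.00 and Serpinf1, the antiangiogenic factor PEDF, by 2.18. Timp1, an inhibitor of metalloproteinases, did not pass (0.28). The list's adjusted p was 2.8e-06, and adjusted p = 0.164 with an estimated correlation.

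Contractile and myofibroblast genes, which build actin stress fibres, had 21 members listed and 17 tested: 14 rose, none fell and 3 did not pass, gene-wide and when adjusted over the list alone. Acta2 had a log2 fold change of 2.06 (SE 0.17, adjusted p = 9.2e-33), Myl9, a myosin light chain, 2.20, and Actg2, the enteric smooth muscle actin, 2.65. The Actg2 counts were low, 29, 20 and 26 in the knockout against 3 and 4 in the wild type. Actin genes are closely alike, and although the counts of Acta2 and Actg2 were whole in every library, reads placed wholly on a wrong copy were not tested. Thbs1, an adhesive matrix protein, was at 0.01 and Smtn, a smooth muscle protein, at -0.29, and neither passed. Both lie opposite other genes, but so do some members that rose: 6 of the 17 tested were called opposite another gene. Cnn1, a calponin, had 33 knockout counts against 3, a ratio of 6.71 (2.10 to 34.2), and Lmod1, an actin nucleator, 31 against 3, a ratio of 6.30 (1.97 to 32.2). The median was 1.16, or 1.07 with those 2 genes at the lower ends of their intervals (adjusted p = 1.0e-11; adjusted p = 0.152 with an estimated correlation). Without wild type 1, 8 members rose, Cnn1 was at 1.57 and Lmod1 at 2.05, neither past the test; without wild type 2, Lmod1 was at 3.16 and did not pass, and Cnn1 was fitted at 6.45 with the wild type at 0 counts. With a knockout library left out, Lmod1 (any of the 3) or Cnn1 (the second or the third) was not tested.

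Among osteoblast genes 22 were listed and 5 tested; 3 rose by either adjustment. Sparc, the bone matrix protein osteonectin, rose from 886 ± 88.5 to 2520 ± 171 CPM. Alpl, the alkaline phosphatase needed for mineral, had 52 knockout counts against 3, a ratio of 10.6 (3.42 to 52.9), and a log2 fold change of 3.29 (fitted at 7.07 without wild type 1, the library with all 3 of those counts). Postn, the matrix protein periostin, rose by 0.91, which was also the list's median (1.46 without wild type 1), while Spp1, osteopontin, was at -0.02 and did not pass (adjusted p = 0.918). The list's adjusted p was 0.00081, and adjusted p = 0.245 with an estimated correlation. Runx2, the master regulator of the lineage, had 18 counts against 9 and was too low to test. Of the chondrocyte genes 10 were listed and 1 tested: Prg4, the joint lubricant, at -0.26 (adjusted p = 0.675; 204 exon bases opposite Tpr), neither gene-wide nor when adjusted over the list alone past the test.

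Adipocyte genes went both ways: 15 were listed, 6 tested, 1 rose and 3 fell by either adjustment, with a median of -0.11 (adjusted p = 0.308). Plin2, the coat protein of lipid droplets, fell 2.70-fold, and Cd36, a fatty acid receptor also found on macrophages, fell by 0.86 on the log2 scale. Cebpd, an early adipogenic factor, rose by 0.92, a call lost without any single library (0.69 to 1.20). Cebpb, another, fell by 1.07, a call lost without knockout 3 (-0.76) or wild type 1 (-0.59). Exons of Cebpd lie opposite Spidr and those of Cebpb opposite Tmem189. The list's median turned with the library left out, but the members tested changed as well. It was -0.79 without knockout 1 (5 tested), 0.03 without knockout 2 (6) and -0.76 without knockout 3 (5). Without wild type 1 it was 0.47 (7 tested) and without wild type 2 0.12 (8).

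Stromal progenitor markers had 21 members listed and 11 tested; 2 rose and 1 fell, or 3 and 1 when adjusted over the list alone (median 0.37, or 0.23 without knockout 3 and 0.09 without wild type 2; adjusted p = 0.131). Cxcl12, the chemokine that holds blood stem cells in marrow, rose from 292 ± 7.82 to 726 ± 66.4 CPM. Itga11, a collagen receptor, rose by 1.19, a call lost without wild type 1 (1.08) or wild type 2 (1.27). Cd44, a hyaluronan receptor of stromal and blood cells, fell by 0.99, a call lost without wild type 2 (-0.89). Pdgfra and Pdgfrb, the growth factor receptors of mesenchymal cells, were at -0.34 and 0.15 and did not pass.

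Of the WNT genes 26 were listed and 7 tested, and 4 rose by either adjustment: Dkk3 and Sfrp1, secreted modulators of the pathway (2.06 and 1.79), Rspo2, which amplifies it (2.03), and Wisp2 (1.34). Ctnnb1, β-catenin itself, was at 0.20 and did not pass. The list's adjusted p was 0.00158, and adjusted p = 0.235 with an estimated correlation; without wild type 1, 2 members rose. Of the BMP and TGF-beta genes 30 were listed and 11 tested, 2 rose and 1 fell, or 3 and 1 when adjusted over the list alone (median 0.68, or 0.34 without knockout 3; adjusted p = 0.124). These were Ctgf, a matricellular growth factor (0.68; 665 exon bases opposite Gm15270), Ltbp2, a fibrillin-binding protein (0.92; 764 opposite D030025P21Rik), and Tgfbr2, the type II receptor (-0.79). Ctgf lost its call without wild type 1 (0.67) or wild type 2 (0.67); Ltbp2 lost it without knockout 2 (1.04), knockout 3 (0.66), wild type 1 (1.08) or wild type 2 (0.77), and Tgfbr2 without those same libraries (-0.75, -0.74, -0.75 and -0.85).

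Of 20 macrophage and monocyte genes listed, 17 were tested, 9 fell, none rose and 8 did not pass; 11 fell when adjusted over the list alone. Lyz2 had a log2 fold change of -0.67 (SE 0.10, adjusted p = 1.8e-10), Ctss, a lysosomal protease of antigen presentation, -0.86 (SE 0.13, adjusted p = 3.0e-09), Cd14, the coreceptor for lipopolysaccharide, -1.18, and Csf1r, the receptor for macrophage growth factor, -0.76. The mannose receptor Mrc1 was at 0.18 and did not pass. The median was -0.59 (adjusted p = 3.8e-06; adjusted p = 0.106 with an estimated correlation). Without wild type 2, 4 members fell, and without knockout 2 or wild type 1, 6 did. Csf1, the ligand of Csf1r, rose by 1.14, a call lost without wild type 2 (1.02).

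**Figure D2:**
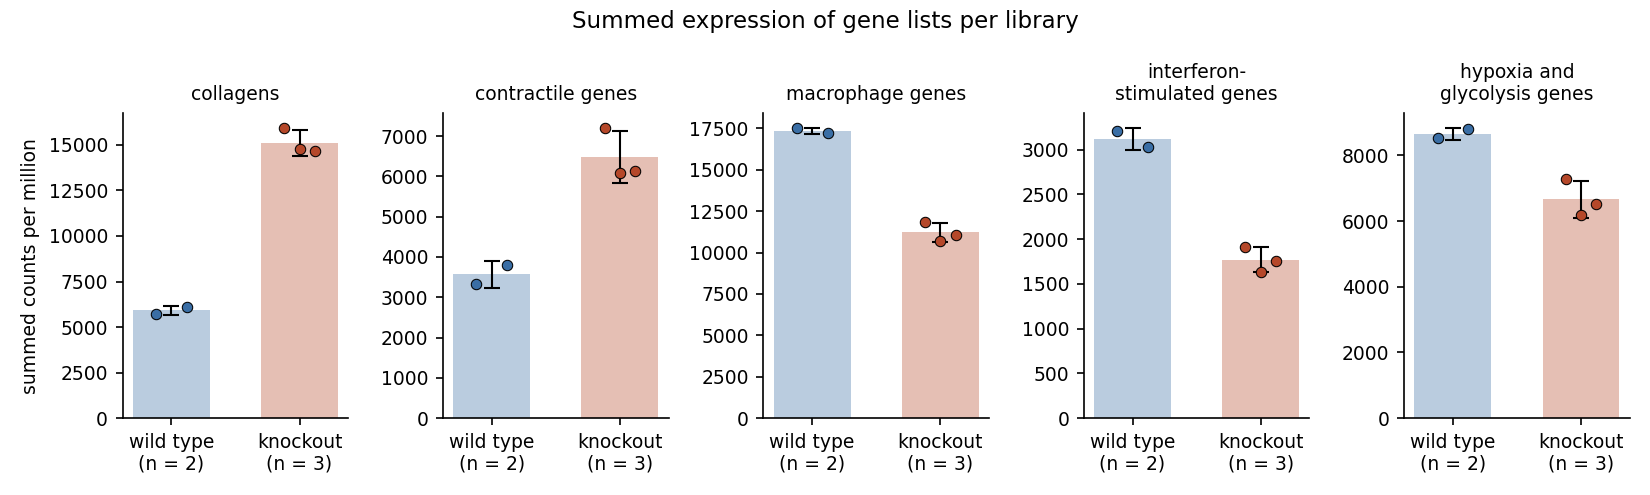
CPM summed over the listed members of 5 gene lists in each library. Points are libraries (2 wild type, 3 knockout), bars the group means and whiskers the SD, on axes that start at 0. Collagen sums lie between 14679 and 15950 in the knockout against 5741 and 6096 in the wild type, and macrophage sums between 10720 and 11862 against 17491 and 17210.

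Markers of other marrow cells were few. Of the osteoclast list 7 were listed and 2 tested: Acp5, the acid phosphatase of bone-resorbing cells that macrophages also make, fell by 1.35 on the log2 scale, also when adjusted over the list alone, a call lost without wild type 1 (-0.89), and Ctsk, the collagenase of osteoclasts, was at -0.61 (adjusted p = 0.225). Pf4, a platelet chemokine, fell by 0.66 as the 1 tested of 6 listed megakaryocyte and mast cell genes. With 1 tested member, adjustment over the list alone changes nothing. The call for Pf4 was lost without knockout 2 (-0.63), wild type 1 (-0.62) or wild type 2 (-0.72). Mmp8, the neutrophil collagenase, was the 1 tested of 5 listed neutrophil genes (-1.12, adjusted p = 0.145) and did not pass. Its edgeR p before any adjustment was 0.0360. Of 10 listed endothelial genes 2 were tested and none passed by either adjustment: Pecam1, an adhesion molecule, was at -0.37 and Emcn, a surface mucin, at 0.01, with a sign that changed between settings. None of the 8 B and plasma cell, 6 T and NK cell, 2 erythroid or 1 skeletal muscle genes listed could be tested; Ebf1, a factor of B cells and stromal progenitors, had 26 counts against 5, Cd8a, a T cell coreceptor, 12 against 10, Alas2, an enzyme of haem synthesis, 1 against 1, and Des, a muscle filament, 2 against 0.

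Interferon-stimulated genes, the antiviral response, had 25 members listed and 19 tested; all 19 had negative log2 fold changes, 6 fell gene-wide and 12 when adjusted over the list alone. Ifit2, which binds viral RNA, fell 3.91-fold and Mx1, an antiviral GTPase, 3.82-fold; Irf7, a factor that induces interferon, fell by 1.12 on the log2 scale, and Isg15, a ubiquitin-like modifier, was at -0.14 and did not pass. The median was -0.68 (adjusted p = 3.6e-05; adjusted p = 0.106 with an estimated correlation). Of the NF-kB targets, cytokines and regulators of inflammation, 27 were listed and 9 tested; 1 rose (Csf1, above) and 4 fell, or 2 and 5 when adjusted over the list alone (median -0.59, adjusted p = 0.0760; adjusted p = 0.242 with an estimated correlation). The list passed without wild type 1 (median -1.004, adjusted p = 0.00314) and without wild type 2 (median -0.94, adjusted p = 0.00194), with more members tested in each. Il1b, a fever cytokine of macrophages, was at -1.91, a call lost without wild type 1 (-1.84) and -3.27 without knockout 3, and Saa3, an acute phase protein, fell by 0.59. Birc3, an inhibitor of cell death, fell by 2.09, a call lost without wild type 2 (-1.92).

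Hypoxia and glycolysis genes had all 28 members listed and 24 tested; 5 fell and none rose, or 11 and 0 when adjusted over the list alone. Vegfa, the endothelial growth factor, fell 2.04-fold, Ndrg1, a stress-response gene, 3.77-fold (556 exon bases opposite Gm17035), and Hk2, a hexokinase, by 1.08 on the log2 scale. Ldha, lactate dehydrogenase, was at -0.19 and Pgk1, a glycolytic kinase, at -0.15; neither passed. The median was -0.43 (adjusted p = 0.00083; adjusted p = 0.161 with an estimated correlation), and without wild type 1, 2 members fell, and without wild type 2 or knockout 2, 3 did. The nuclear-encoded respiratory chain had 28 listed and 12 tested, none past the test by either adjustment with edgeR and 2 at an unadjusted p under 0.05: Atp5o (1.21; 702 exon bases opposite Gm15976) and Atp5a1 (0.50; 129 opposite Haus1), both subunits of ATP synthase, had the smallest p (adjusted p = 0.169 and 0.174), and the list's adjusted p was 0.533. Of the NRF2 and antioxidant genes 25 were listed and 14 tested, 2 rose and 1 fell, or 2 and 2 when adjusted over the list alone (median -0.19, or -0.12 without knockout 2, -0.11 without wild type 1 and -0.41 without wild type 2; adjusted p = 0.724). Slc7a11, the cystine importer, rose 2.09-fold, Gpx3, a secreted peroxidase, 1.62-fold, a call lost without wild type 1 (0.59 on the log2 scale), and Hmox1, which breaks down haem, fell 2.07-fold.

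Cell cycle genes had 37 members listed and 8 tested, and 2 rose by either adjustment (median 0.31, adjusted p = 0.131): Tyms, which makes thymidylate (0.62, a call lost without wild type 2 at 0.57), and Kif20a, a mitotic kinesin (0.77; 1271 exon bases opposite Cdc23), a call lost without knockout 3 (0.68), wild type 1 (0.78) or wild type 2 (0.74). Mki67, the proliferation marker, was at -0.46 and did not pass. Of the cell cycle inhibitors and senescence genes 19 were listed and 10 tested, and 4 rose by either adjustment (median 0.45, adjusted p = 0.0180; adjusted p = 0.192 with an estimated correlation; 2 rose without wild type 1 or wild type 2). They were Igfbp7 (1.61), Igfbp5 (1.30) and Igfbp4 (0.88), binding proteins of insulin-like growth factors, and Ccng1, a p53 target (0.69); Cdkn1a, the inhibitor p21, was at 0.32 and did not pass. The unfolded protein response had all 20 listed and 13 tested, of which Pdia3, a disulfide isomerase (0.48), and Calr, a chaperone of the endoplasmic reticulum (0.38), rose by either adjustment; the list's median was 0.35 and its adjusted p 0.226. Both calls were lost without knockout 3 (0.44 and 0.35), wild type 1 (0.49 and 0.42) or wild type 2 (0.45 and 0.33). Of 22 listed cholesterol genes 4 were tested and none passed by either adjustment: Sqle and Fdft1, enzymes of squalene, were at 0.65 and -0.24 (774 exon bases of Fdft1 opposite Ctsb).

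**Figure D3:**
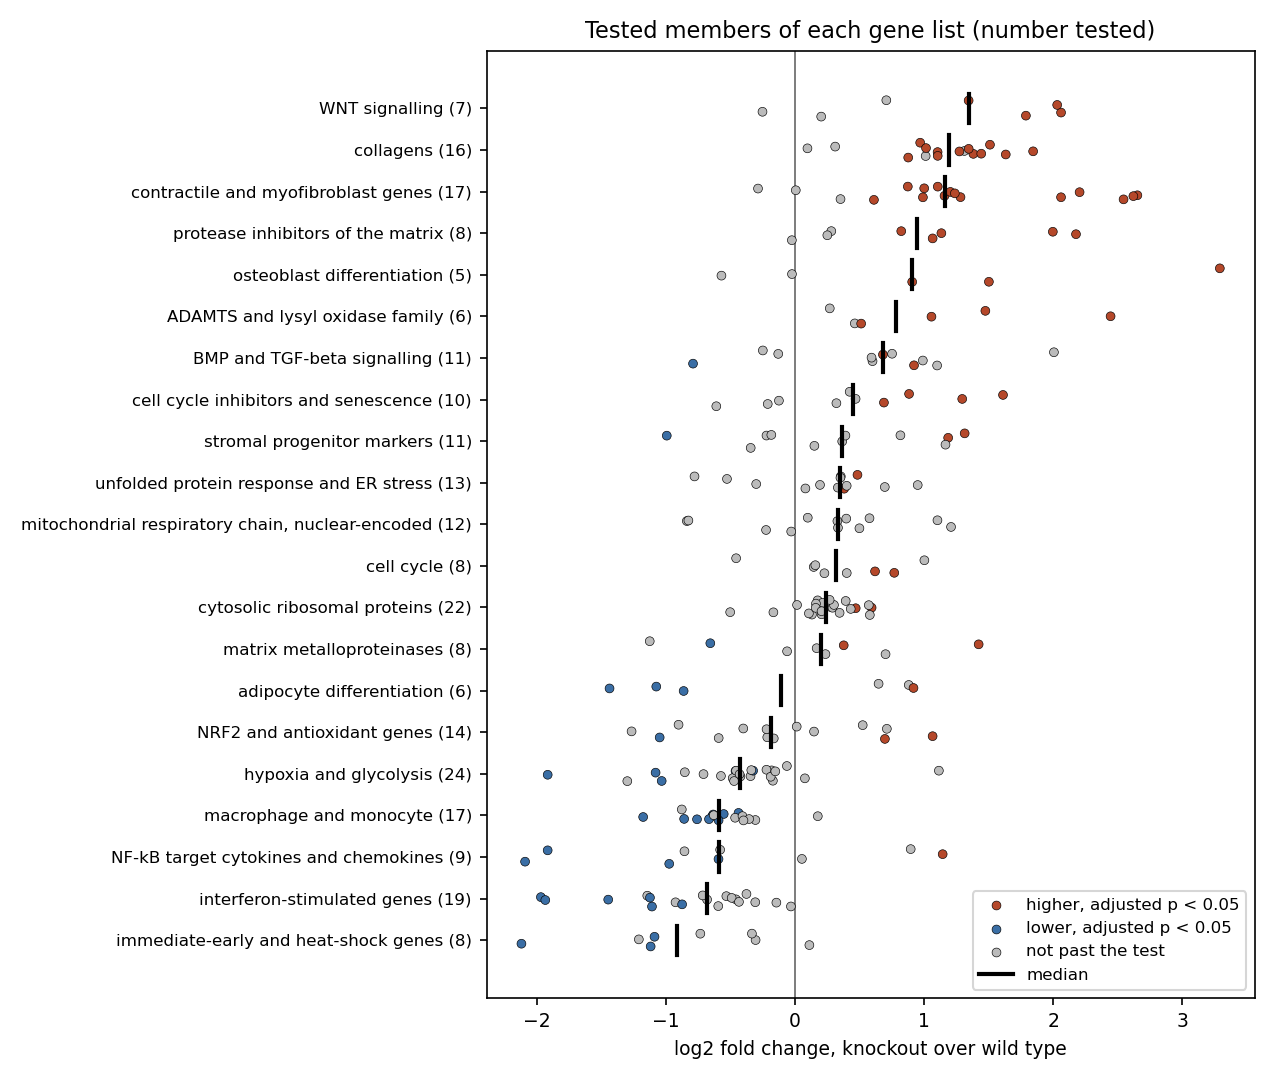
Log2 fold change (knockout over wild type) of each tested member of the 21 gene lists with at least 5 tested genes, from edgeR on 3 knockout and 2 wild type libraries. Points are genes, red where higher and blue where lower at an adjusted p under 0.05, grey otherwise, and black ticks the list medians, with the number tested in brackets; medians run from -0.91 for immediate-early and heat-shock genes to 1.34 for WNT signalling.

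Lists that report on handling and RNA were also read. Of the immediate-early and heat-shock genes, switched on within minutes of a stimulus, 19 were listed and 8 tested: 3 fell and none rose, or 4 and 0 when adjusted over the list alone (median -0.91, adjusted p = 0.0164; adjusted p = 0.235 with an estimated correlation and 0.0608 without knockout 1, where the list did not pass). Fos, a subunit of AP-1, fell 4.34-fold, Egr1, an early transcription factor, fell by 1.09 on the log2 scale and Junb, another AP-1 subunit, was at -1.12, a call lost without wild type 2 (-0.89); 1 member fell in the fit without wild type 2. Ribosomal protein genes had 24 listed and 22 tested, 2 rising gene-wide and 0 when adjusted over the list alone (median 0.24, adjusted p = 0.0982, or 0.0310 without genes opposite another gene and 0.0481 without knockout 2): Rpl23 at 0.59 and Rpl4 at 0.47, parts of the large subunit. Rpl23 lost its call without knockout 1 (0.43), knockout 3 (0.58), wild type 1 (0.42) or wild type 2 (0.74), and Rpl4 without knockout 1 (0.45), knockout 2 (0.44), wild type 1 (0.45) or wild type 2 (0.47). Of 5 listed histone genes 1 was tested, Hist1h1c, a linker histone, at -0.84 (adjusted p = 0.185, past the test at -1.47 without wild type 1 and at 0.10 without wild type 2). None of the 13 mitochondrially encoded genes was listed. Of the sex-linked genes, Ddx3y, a Y-linked helicase, had 9, 12 and 12 counts in the knockout and 8 and 18 in the wild type, Eif2s3y, a Y-linked translation factor, 12, 12 and 5 against 5 and 6 (neither past the test), and Xist, the RNA of the inactive X, 0, 0 and 0 against 1 and 0.

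Outside the lists, the largest rises named by the rule were those of Dpysl3, Ttc13, Phyhipl, Cnn3, Psg17 and Pcolce. Psg17, a pregnancy-specific glycoprotein with close relatives (its counts were whole in every library, but reads placed on a wrong copy were not tested), rose from 177 ± 64.8 to 1046 ± 109 CPM (log2 fold change 2.58, SE 0.18, adjusted p = 6.0e-43). Pcolce, which enhances the enzyme that trims procollagen, rose by 2.49 (112 exon bases opposite Gm36266), and Cnn3, a calponin, by 2.68 (4.30 without wild type 2; 538 opposite Gm42928). Phyhipl rose by 2.79, but 1055 of its exon bases lie opposite Fam13c. Dpysl3, a cytoskeletal protein of neurites, had 32 counts against 1, a ratio of 19.5 (3.26 to 794), and a log2 fold change of 3.98 (fitted at 6.37 without wild type 1, with the wild type at 0 counts). Its call was lost without wild type 2 (3.20), and it was not tested without knockout 2 or knockout 3. Ttc13 had 37 counts against 3, a ratio of 7.52 (2.38 to 38.1), with the call lost without wild type 2 (2.49) and no test without knockout 2 or knockout 3.

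Among the largest falls named by the rule, Gzmg, a granzyme (a protease of cytotoxic granules, likewise with close relatives and whole counts), had 35 and 27 counts in the wild type and 0, 0 and 1 in the knockout, a wild type to knockout ratio of 102 with an interval of 17.6 to 4081 (log2 fold change -6.21, adjusted p = 6.7e-19). Irg1, which makes itaconate in activated macrophages, fell 5.21-fold, a call lost without wild type 1 (-2.10 on the log2 scale). Gbp4, an interferon-induced GTPase, fell 4.33-fold, and Best1, a chloride channel, 4.81-fold. Sema4d, a semaphorin of immune cells and osteoclasts, was at -2.37, Cxcr4, the receptor of the Cxcl12 protein, at -2.09, and Slfn1, a regulator of lymphocyte growth, at -2.05. All 3 lost their calls without wild type 1 (-2.44, -2.14 and -1.96) or wild type 2 (-2.35, -2.05 and -2.18), and Slfn1 also without knockout 2 (-1.50), while it was at -3.18 without knockout 3. Ovca2 fell by 2.84, with 641 exon bases opposite 1700016P03Rik.

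Terms that the files attach to genes were tested among the higher and the lower genes with a hypergeometric test, and 41 of 1345 passed for the higher and 16 for the lower genes, or 58 and 47 with all listed genes as background. Among the higher genes the 3 smallest adjusted p were those of cardiomyopathy pathways, with 32 of 87 tested genes for the hypertrophic form (adjusted p = 3.8e-11). ECM-receptor interaction, the pathway linking matrix to integrins, held 27 of the higher genes among its 73 tested (adjusted p = 1.3e-09), collagen fibril organization 10 of 18 (adjusted p = 2.2e-05) and basement membrane 12 of 30 (adjusted p = 9.7e-05). Also past the test there, leukocyte transendothelial migration held 30 of 126 (adjusted p = 4.3e-06), phagosome 31 of 156 (adjusted p = 0.000108) and hematopoietic cell lineage 17 of 66 (adjusted p = 0.000672). Extracellular space passed in both directions, with 55 higher (adjusted p = 4.1e-09) and 39 lower genes (adjusted p = 0.0109) of 264. Among the lower genes, external side of plasma membrane held 21 of 70 (adjusted p = 7.3e-05), cellular response to lipopolysaccharide 14 of 43 and inflammatory response 15 of 50 (both adjusted p = 0.00156).

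Of 66 named genes past the test, 35 passed it with each library left out in turn, while leaving out wild type 1 or wild type 2 reduced the genes higher to 144 or 153 and the genes lower to 154 or 146. Nothing in the sources used here says that the libraries of a group came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical. That spread was small. Chi-square over its degrees of freedom, near 1 for counting error alone, was 1.37 to 1.63 between libraries of a group. Between libraries of different groups it was 5.51 to 5.99.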

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

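The settings that left out genes opposite another gene or kept only genes with whole counts were chosen after the data were seen, and the others were fixed before. The first of these also left out 169 tested genes with no exon model, of which 35 were called in the fit of all genes. Across RLE, upper-quartile and total-count scaling the genes higher ranged from 289 to 314 and the genes lower from 283 to 316. Fewer were called with DESeq2 (172 higher, 134 lower; it gave no adjusted p for 10986 genes), limma-trend on log2(FPKM + 1) (78 and 66), the same unfiltered (80 and 70) or with 0.1 added (68 and 50), a fold of 1.5 as the null (92 and 66), an adjusted p under 0.01 (196 and 186) and without genes opposite another gene (158 and 165). The fold of 1.5 and the 0.01 are stricter thresholds. Of the genes kept in the last setting 159 were higher and 196 lower in the fit of all genes, so removing genes accounts for only part of the drop in lower genes; the other causes were not tested. Leaving out 1 library gave 144 to 323 higher and 146 to 287 lower genes, lowest with 1 wild type library left, whose spread is then taken from the knockout.

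The replicate numbers did not pair the libraries (correlation of same-numbered deviations over genes 0.011). With the number as a block 229 genes were higher and 212 lower, and Mmp3 was at 1.42 and did not pass (adjusted p = 0.0594). Mmp3 also stayed higher without passing with DESeq2 (1.46), voom (1.36), log2(FPKM + 1) (1.35), the same unfiltered (1.35), log2(FPKM + 0.1) (1.41), no count filter (1.45) and the fold of 1.5 (1.42), with adjusted p from 0.0675 to 0.163; over single libraries left out it ranged from 1.28 to 1.57. The cause was not tested.

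Lists past the test numbered 11, 0 with an estimated correlation, 18 with fry and 10 to 12 with 1 library left out. Terms past the test numbered 57, and 105 with all listed genes as background. The Arntl ratio ranged from 0.456 to 1.07 with 1 library left out; without wild type 1 no ratio could be formed. The odds ratio near Arntl was 0.260 within 10 Mb, 0.255 within 5 Mb and 0.511 within 20 Mb, and Arntl itself was not among the tested genes. Among genes not past the test, signs turned for Csnk1d with the block (0.026) and without knockout 3 (-0.44 to 0.034 over single libraries left out), Nr1d1 without knockout 2 (-0.11 to 0.44), Ddx3y (-0.96 to 0.39) and Hist1h1c (-1.47 to 0.10) without wild type 2, and Nr1d2 with voom (0.12), log2(FPKM + 1) (0.29, also unfiltered), log2(FPKM + 0.1) (0.38) and without wild type 2 (-0.87 to 0.96). Emcn turned with upper-quartile scaling (-0.0079), voom (-0.0050), log2(FPKM + 1) (-0.025, also unfiltered), log2(FPKM + 0.1) (-0.027), whole counts only (-0.012) and without knockout 1 or wild type 1 (-0.10 to 0.088); the cause was not tested. No surrogate variable was found (0), so that fit was not run. With 211623 to 281990 counts per library, changes under 2-fold were mostly missed: 17.0% of 1.5-fold changes were recovered in simulated data.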

Other observations

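The genes and tests below were chosen after their values were seen, except the term test and the count of calls near Arntl, which were planned before the data were examined (the bound of the second was set afterwards). Several abundant genes outside the lists were lower in the knockout libraries. Apoe, a carrier of cholesterol, fell from 6778 ± 217 CPM (SD, n = 2) to 3144 ± 250 (n = 3), Abca1, which exports cholesterol, fell by 1.68 on the log2 scale (adjusted p = 2.0e-13), and Fth1, the iron store ferritin, by 0.75. Arg1, which breaks down arginine, fell by 1.58, Gpnmb, a lysosomal glycoprotein, by 1.35, C3, the central complement protein, by 1.28, and Mpeg1, a pore-forming protein of phagocytes, by 0.98. The term lysosome held 15 lower genes among 71 tested (adjusted p = 0.0399).

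Other genes outside the lists were higher. Bgn, the matrix proteoglycan biglycan, rose from 377 ± 15.2 to 908 ± 72.2 CPM, and Ogn, the small proteoglycan osteoglycin, by 1.80 on the log2 scale. Thbs2, a matricellular regulator, rose by 1.46, Aebp1, a collagen-binding protein, by 1.64, and Cdh11, the cadherin of mesenchymal cells, by 1.37. Fbln5, which organises elastic fibres, rose by 2.35 on low counts, 25, 20 and 24 in the knockout against 4 and 4 in the wild type. Granzyme genes, which lie together on chromosome 14, did not move alike. Gzmd had 26 knockout counts against 56 in the wild type (log2 fold change -1.82, adjusted p = 3.8e-05), Gzmb 3 against 23 (ratio 0.0795, exact Poisson interval 0.0153 to 0.263) and Gzmf 0 against 11 (ratio 0, interval up to 0.243; 151 exon bases opposite another gene), while Gzme had 154 against 55 (0.76, adjusted p = 0.0314; lost without any single library but knockout 3, at 0.67 to 0.84). These genes are close copies; their counts were whole in every library, but reads placed wholly on a wrong copy were not tested, so each one's level stays uncertain.

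Of the collagens 12 of 16 rose and of the macrophage genes 9 of 17 fell, although neither list passed with an estimated correlation (adjusted p = 0.106 for each). A smaller share of macrophages in the knockout cultures is a candidate explanation beside the genotype itself. Cell shares were not measured, and the fold changes bear on them only indirectly. The lowest collagen median over 4 scalings was 1.17, and the macrophage medians stayed between -0.61 and -0.57. These scalings hardly differed (overall median log2 fold change -0.0076 to 0.025), so that stability decides little. A scaling shift would move both lists the same way, but they lay on opposite sides of 0, which argues against scaling as the cause of both. A smaller macrophage share would raise the collagens alike if the other cells were 1 uniform type that alone made collagen, which was not tested. The collagens' log2 fold changes ran from 0.10 for Col16a1 to 1.84 for Col8a1, beyond their errors (Cochran's Q across genes, chi-square p = 0.00102). For the contractile genes, from -0.29 for Smtn to 2.65 for Actg2, 90.0% of the spread lay beyond error. For the stromal progenitor markers, from -0.99 for Cd44 to 1.31 for Cxcl12, that share was 86.2%. Smtn lies opposite another gene, and Cd44 is also made by blood cells. Both lists too would move alike only if that 1 type alone made their products. The errors may hold technical spread alone, and other shifts in cell make-up stay open. A smaller share of macrophages is thus argued against as the whole cause of the changes in these lists only in this simple case. For the fall of the macrophage genes it cannot be told apart from regulation: the 17 genes, of which 3 (Cd14, Cd68 and Ctss) are also made by mesenchymal cells, differed around a shared -0.59 with a p of 0.0502 in the same test and 39.1% of their spread beyond error.

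Mmp3 rose by an amount close to that of the collagens, and may have risen only along with them. Its log2 fold change lay 0.23 above the collagen median of 1.19, with an interval of -0.68 to 1.15, so a rise of its own cannot be told apart from the shared one with 54 knockout and 12 wild type counts.

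Genes whose exons lie opposite another gene made up 25.9% of genes with an exon model but held 48.9% of the counts (48.1%, 50.5% and 50.6% in the knockout, 47.6% and 47.5% in the wild type libraries), and they were 61 of the 100 genes with most counts. Bace1 alone, a protease of nerve cells, held 4.26% of all counts. Some pairs, picked after their counts were seen, were very unequal: Mterf4 had 7119 counts against 89 for Sned1 on the other strand. Likewise Snx22 had 6814 against 204 for Ppib, Myo1h 4293 against 89 for Kctd10 and Map3k12 3399 against 329 for Pcbp2. Unc13a had 2698 against 65 for Colgalt1, and Phyhipl 428 against 10 for Fam13c. One candidate explanation is that reads of one gene were counted for the gene opposite. The unequal pairs go with it but, being picked, do not test it. Fold changes of 226 overlapping pairs correlated across genes, which are not independent replicates, at a Spearman rho of 0.28. For 165 neighbouring pairs within 5 kb the rho was 0.27. The difference of 0.0087 had an interval of -0.18 to 0.20, too wide to decide on that explanation, which stays open. Reads shared with near-identical genes also stay open, since 28.9% of those counts sit in genes with a count that is not whole; no biological explanation was tested.

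A knockout bred from another strain may keep donor sequence round the target and so misread genes there. Within 10 Mb of Arntl 2 of 41 tested genes were called, against 604 of 3669 elsewhere (odds ratio 0.260, two-sided Fisher's exact interval 0.0304 to 1.01, p = 0.0529), which argues against an excess of calls near the gene.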
